A study of Homo sapiens with 36 samples.

How the data were processed

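RNA was sequenced from 36 libraries of 2 established human cell lines, 22Rv1 (prostate carcinoma) and MCF7 (breast carcinoma). Each line carried either a control guide RNA (sgControl) or a guide against the gene NONO (sgNONO), and each was given the solvent DMSO, SKBG-1 (R) or SKBG-1 (S) for 4 h. The labels give doses of 20 µM in 22Rv1 and 5 µM in MCF7, DMSO at 0.04%, and biological triplicates, so that each line held 6 groups of 3 libraries. The column names of the treated libraries in both count tables carry the number 10, which the labels do not explain, and the labels' doses are used here. Nothing says whether the triplicates came from separate cultures, so p-values may measure in part technical spread. Each line has 1 code for sgControl and 1 for sgNONO in the column names, so the effect of a guide cannot be separated from that of a single clone or pool. Per the labels' protocols, RNA was extracted with the QIAGEN RNeasy Plus mini kit and libraries were made with the NEBNext Ultra RNA kit.

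Per the submitters' processing notes, Salmon 1.3.0, DESeq2 1.30.1, STAR and the builds hg38 and hg19 were used; their roles, the annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene for each line, with 60232 genes for 22Rv1 and 60215 for MCF7, and no normalization of them is described. If these counts came from Salmon they are rounded estimates, in which reads of near-identical genes are shared out by a model. The column names gave each library's group and replicate number, and 0 columns of other samples were present. Without a stated strand setting, overlapping and antisense genes were treated as not separable. For 22Rv1 the authors also deposited splicing tables of 6 comparisons, per the file headers made with rMATS, whose version is not given in the sources used here. They hold 5 event types with, per the file headers, junction read counts and inclusion levels for the 3 libraries of each group, and the p-value and false discovery rate of the authors' own test. The deposited inclusion differences matched the differences of the deposited group means to within 5e-04 of the inclusion level.

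Gene counts were tested per line in 1 fit of 18 libraries with 6 groups, without covariates, so that all comparisons shared 1 estimate of the spread with 12 residual degrees of freedom. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, its default expression filter and the quasi-likelihood test. That filter kept 18231 genes in 22Rv1 and 17746 in MCF7, among them genes without a symbol, of which the tables hold 36 each. The common dispersion was 0.00233 in 22Rv1 and 0.01954 in MCF7. A gene was called when the Benjamini-Hochberg adjusted p over all genes of a comparison was under 0.05, and all adjusted p values of genes come from this test unless another tool is named. Symbols shared by several gene identifiers (1037 entries in 22Rv1 and 1020 in MCF7) were kept as separate genes. Differences are log2 fold changes ± their standard error, levels are CPM ± SD over 3 libraries, and a fold against a group with 0 counts is a lower bound at 3 counts over the group. Count ratio intervals and floors cover counting error only, and bootstrap intervals cover the sampling of genes, not of libraries.

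The 24 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives not named below as later choices. They cover DBHS proteins (the family of NONO, SFPQ and PSPC1) with paraspeckle components, lineage transcription factors, androgen response, estrogen response, NRF2 targets, heat shock response, the ATF4 integrated stress response, the unfolded protein response, p53 targets, immediate early genes, NF-kB targets, interferon-stimulated genes, hypoxia targets, cholesterol synthesis, S phase, G2 and mitosis, MYC targets in ribosome biogenesis, DNA repair, splicing factors, mitochondrially encoded mRNAs, replication-dependent histones, markers of each line, and fibroblast and blood cell markers. They were written from general knowledge and tested with limma 3.58.1's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists of a comparison. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

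Named genes followed a rule: among called genes with a symbol that is not a clone name, a mean of at least 5 CPM in the higher group and all 3 libraries of a group above or below all of the other, the 12 largest rises and 12 largest falls for SKBG-1 (R) against DMSO in sgControl cells and 5 of each for other comparisons; up to 4 called members of each list by size of change at 5 CPM or more, or up to 2 of the most abundant where none was called; and NONO, SFPQ, PSPC1, MYC, AR in 22Rv1 and ESR1 in MCF7 in every comparison. Members of this set are left out of the text in places for length. Gene positions are from GENCODE v29 on GRCh38, in which 96.3% of the gene identifiers of each table were found. Of the 80555 upstream exons in the skipped-exon table of SKBG-1 (R) against DMSO, 96.1% were identical to an exon of that annotation, so its build was used for the splicing coordinates.

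A splicing event was counted when the authors' false discovery rate was under 0.05, the inclusion levels differed by at least 10 points of percent and inclusion plus skipping reads averaged at least 10 per library in both groups. The 5 named events per comparison had at least 20 reads and the largest differences, 1 per gene. The authors' rate comes from their own test on the junction reads of 3 libraries per group. How that test weighs the spread between libraries was not examined here. As a second test, limma was run on the log2 ratio of inclusion to skipping reads, each with 0.5 added. Chosen after the data were seen, limma was also run with precision weights for events with both forms at 5 reads or more.

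Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0 as the test, no expression filter, only the groups compared in the fit, the replicate number as a block, a fold minimum of 2, each library left out in turn, and for splicing other thresholds, no coverage minimum and limma. Chosen after the data were seen were the removal of genes present in single libraries and a minimum of 5 CPM. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

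The tests were checked on simulated counts drawn from the real means and library sizes. For SKBG-1 (R) against DMSO in sgControl 22Rv1, 65.2%, 68.2% and 87.7% of genes changed by 1.5, 2 and 4 times were called, with 9 false calls in 17881 genes tested. For the same comparison in MCF7 the shares were 47%, 66.1% and 83.3%, with 6 false calls in 17336 tested. Few genes were changed (66, 66 and 65 in 22Rv1), with rises and falls balanced. The real comparison in 22Rv1 called 52.1% of genes, with 229 rises and 1753 falls of at least 2-fold. The simulations therefore do not test TMM scaling under such a broad change, and fold changes are relative to that scaling. The limma test of splicing with weights called 0%, 16.4% and 53% of simulated differences of 10, 20 and 40 points in 32112 events, and without weights 0%, 0% and 19.7% in 33861 events, with 0 false calls. The spread between libraries in the splicing simulation was a fixed choice, not estimated from these data, so the shares may differ for the real libraries. In every group the counts of each pair of libraries differed by more than sampling noise, with chi-square values per gene of at least 2.44, so none was counted as a duplicate.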

Results

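Gene expression was measured by RNA sequencing in 22Rv1 and MCF7 cells, which depend on the androgen receptor and the estrogen receptor as lineage factors. The series title speaks of ligands of NONO, an RNA-binding protein of the DBHS family that takes part in transcription, splicing and paraspeckles, and of control compounds. In each line, sgControl and sgNONO cells received DMSO, SKBG-1 (R) or SKBG-1 (S) for 4 h, in 6 groups of 3 libraries. Total gene counts per library were 21237515 to 31447330 in 22Rv1 and 20785103 to 50726251 in MCF7. Mitochondrially encoded transcripts took 3.92% to 8.11% and 1.02% to 9.37% of them. In MCF7, 1 unnamed gene, AC010970.1, took 1.13% and 1.17% of counts in sgNONO DMSO replicate 1 and sgNONO SKBG-1 (R) replicate 2. The mitochondrial share of 1.02% was that of sgNONO DMSO replicate 2.

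NONO (ENSG00000147140.17, chromosome X 71283192 to 71301168, plus strand) was lower in every sgNONO library than in every sgControl library of its line. In 22Rv1 the sgControl libraries held 371.6, 359.1 and 368.3 CPM with DMSO, 442.7, 439.5 and 429.7 with SKBG-1 (R) and 408.4, 389.2 and 390.3 with SKBG-1 (S). The sgNONO libraries of that line held 33.12, 30.66 and 29.08 CPM with DMSO, 46.29, 47.68 and 44.7 with SKBG-1 (R) and 39.03, 34 and 34.9 with SKBG-1 (S). In MCF7 the sgControl values were 407.8, 432.3 and 428.4 CPM with DMSO, 488.2, 499 and 455.3 with SKBG-1 (R) and 389.8, 392.9 and 398.2 with SKBG-1 (S). MCF7 sgNONO libraries kept 193.6, 144.6 and 192.3 CPM with DMSO, 199.8, 202.8 and 192.2 with SKBG-1 (R) and 155.7, 180.8 and 171.5 with SKBG-1 (S). Between DMSO groups NONO was 11.8-fold lower in 22Rv1 (log2 fold change -3.56 ± 0.05) and 2.39-fold lower in MCF7 (-1.26 ± 0.10). A change in mRNA level does not measure the protein. The labels do not say whether the sgNONO cells were a mixture of edited and unedited cells, so the sgNONO and interaction values of MCF7 hold for a population that kept this NONO mRNA.

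The first question was what SKBG-1 (R) changed in sgControl 22Rv1 cells. AR, the androgen receptor (chromosome X 67544032 to 67730619, a span of 187 kb), fell 2.22-fold, from 278 ± 8.79 CPM to 125 ± 1.46 CPM (SD, n = 3; log2 fold change -1.15 ± 0.03, edgeR adjusted p = 2.36e-16). The NONO paralogs rose, SFPQ by 0.99 ± 0.04 on the log2 scale and PSPC1 by 0.67 ± 0.04. NONO itself rose by 0.26 ± 0.04, and MYC changed by -0.28 ± 0.05. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 107-fold from 6.77 ± 2.51 to 722 ± 66.1 CPM (6.74 ± 0.19). Other large rises were in CHAC1 (4.91 ± 0.17), which degrades glutathione, the heat shock gene HSPA6 (4.29 ± 0.30), OSGIN1 (3.89 ± 0.06), DDIT3 (3.82 ± 0.17), HSPA1A (3.77 ± 0.22) and DDIT4 (3.66 ± 0.15). Others were ATF3 (3.26 ± 0.17), SESN2 (2.85 ± 0.10), HSPA1B (2.84 ± 0.15) and GDF15 (2.79 ± 0.09). HSPA1A and HSPA1B are nearly identical, so the split of reads between them is uncertain. SFT2D3, a gene of 1 exon inside another annotated gene on chromosome 2, had 0 counts in the DMSO libraries and 7.47 ± 0.785 CPM with SKBG-1 (R), at least 210-fold higher. Its reads may not be separable from those of the surrounding gene.

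Large falls in the same comparison were in genes of long span and, with larger standard errors, in 4 genes of shorter span. ZSWIM6 (214 kb) was 12.4-fold lower (log2 fold change -3.64 ± 0.16) and BTRC (203 kb), a substrate receptor of an SCF ubiquitin ligase, was 12.2-fold lower (-3.61 ± 0.15). The zinc finger and homeobox gene ZHX2 (-3.56 ± 0.13), FAM110B (-3.52 ± 0.07) and the Wnt pathway ligase gene ZNRF3 (-3.41 ± 0.12) fell. The potassium channel gene KCNJ3 (-3.38 ± 0.14), the transcription factor E2F3 (-3.31 ± 0.10) and LIN52 (-3.29 ± 0.10) fell alike. SPP1 (7.78 kb, -4.78 ± 1.3), IGFBP7 (79.6 kb, -4.03 ± 1.0), C3 (52.9 kb, -3.92 ± 1.1) and TGFBI (34.9 kb, -3.29 ± 0.71) also met the rule for named genes. These 4 had group means of 5.7 to 22 CPM in sgControl DMSO and of at most 1.05 CPM in sgNONO DMSO. SPP1 had 3.84 ± 6.0 CPM with SKBG-1 (S), most of it in part of the libraries. The standard errors of these 4 genes were 0.71 to 1.3, against 0.07 to 0.16 for the other falls named here. Whether reads from other samples, as weighed in the third pattern below, contribute to these 4 was not tested. Of 18231 genes tested, 4576 were higher and 4922 lower with SKBG-1 (R), 52.1% of genes, by edgeR's quasi-likelihood test. With a fold minimum of 2, 229 were higher and 1753 lower.

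Stress and metabolic gene groups rose together in sgControl 22Rv1 with SKBG-1 (R). Of 23 NRF2 targets, genes of the oxidative stress response, 19 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 1.44e-27), among them GCLM (1.73) and SRXN1 (1.71). Of 24 genes of the ATF4 integrated stress response 22 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.03e-32). All 18 genes of the unfolded protein response rose, adjusted over the list alone too (camera adjusted p = 2.86e-19), with HERPUD1 at 2.52, DNAJB9 at 1.86 and the ER chaperone gene HSPA5 at 1.26. Heat shock genes rose in 19 of 20 cases with 1 fall by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 4.09e-16), including DNAJB1 (1.82) and BAG3 (1.36). Of 21 genes of cholesterol synthesis 20 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 7.36e-35), among them MSMO1 (1.69), INSIG1 (1.61), HMGCS1 (1.36) and MVK (1.29). The DBHS and paraspeckle list had 10 of 14 genes higher and 2 lower, also adjusted over the list alone (camera adjusted p = 2.32e-09), with CPSF6 at 0.94 and MATR3 at 0.62. Of 24 MYC targets in ribosome biogenesis 19 rose and 0 fell by either count, adjusted over the list alone or over all genes (camera adjusted p = 4.7e-06). Each of these 7 lists was also called with an estimated correlation.

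Lineage transcription factors moved the other way. Of 17 tested, 11 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.16e-05, 0.00635 with an estimated correlation). TRPS1 (401 kb), a repressor of the GATA family, fell by 2.99 ± 0.10 on the log2 scale, ETV1 by 1.24 and the prostate homeobox gene NKX3-1 by 1.12. Of 24 androgen response genes 9 fell and 6 rose, also adjusted over the list alone, with PMEPA1 at -1.53, PLPP1 at -1.04 and TMPRSS2 at -0.90. The androgen list as a whole was not called (camera adjusted p = 0.0541, 0.231 with an estimated correlation). Breast line markers had 3 of 11 higher and 4 lower by both counts, over all genes and adjusted over the list alone, and were called down (camera adjusted p = 0.0125). Prostate line markers had 3 of 12 higher and 4 lower by both (camera adjusted p = 0.0907), and fibroblast and blood cell markers 1 of 11 higher (camera adjusted p = 0.694).

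Among the other lists in this comparison, p53 targets had 13 of 25 higher and 7 lower (14 and 8 adjusted over the list alone; camera adjusted p = 0.000644), with BBC3 at 0.95 and SUSD6 at -0.81. Immediate early genes had 14 of 27 higher and 6 lower by both counts (camera adjusted p = 0.000293), with KLF2 at 1.88, JUN at 1.84 and JUND at 1.45. S phase genes had 18 of 28 higher and 3 lower (19 and 3 adjusted over the list alone; camera adjusted p = 0.00271). The splicing factor list was not called (15 of 31 higher, 6 lower, also adjusted over the list alone; camera adjusted p = 0.442). Within it SRSF4, a serine- and arginine-rich splicing factor, fell by 2.36 ± 0.05, TRA2B by 0.62, and the kinase gene CLK1 rose by 0.47. Not called as lists were NF-kB targets (2 of 17 higher, 9 lower; TNFAIP2 -1.09, IRF1 -0.69; camera adjusted p = 0.297) and hypoxia targets (8 of 21 higher, 7 lower; VEGFA 1.17; camera adjusted p = 0.28). Nor were mitochondrially encoded mRNAs (9 of 13 higher, 10 adjusted over the list alone; camera adjusted p = 0.0541) and interferon-stimulated genes (1 of 20 higher, 7 lower; camera adjusted p = 0.527). DNA repair genes (8 of 26 higher, 5 lower; camera adjusted p = 0.617) were not called. Estrogen response genes (7 of 27 higher, 10 lower, or 11 lower adjusted over the list alone; median -0.28 and mean -0.17 but test direction up; camera adjusted p = 0.617) were not called either. The same held for G2 and mitosis genes (5 of 26 higher, 9 lower; camera adjusted p = 0.986) and for histones (0 of 10 called by edgeR over all genes or adjusted over the list alone; camera adjusted p = 0.986). Where a single pair of counts is given, that adjusted over the list alone was equal.

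The same question in MCF7, at 5 µM, gave related genes. ESR1, the estrogen receptor (chromosome 6 151656691 to 152129619, 473 kb), fell 2.88-fold, from 167 ± 10.1 to 58 ± 1.05 CPM (SD, n = 3; log2 fold change -1.52 ± 0.09, edgeR adjusted p = 4.74e-10). PSPC1 rose 3.01-fold (1.59 ± 0.09), SFPQ by 0.80 ± 0.07 and MYC by 0.55 ± 0.13 (edgeR adjusted p = 0.00416). NONO was not called (0.19, edgeR adjusted p = 0.172). HMOX1 rose 17-fold (4.09 ± 0.18), and OSGIN1 (2.80 ± 0.12), the secretory cell factor BHLHA15 (2.43 ± 0.17), IGF2 (1.81 ± 0.25) and DNAJB9 (1.67 ± 0.12) rose. Then came FOSL1 (1.65 ± 0.19), TTC32 (1.55 ± 0.14), FSBP (1.5 ± 0.14), SRXN1 (1.44 ± 0.11) and CUTC (1.44 ± 0.11). IGF2 and FSBP overlap other annotated genes. SFT2D3 had 5 counts in the DMSO libraries and 2682 with SKBG-1 (R), a ratio of 443 per total count with a 95% counting interval of 190 to 1370 (edgeR adjusted p = 0.000668). Large falls were in BTRC (21.3-fold lower, -4.41 ± 0.14), PDZRN3 (-4.30 ± 0.22), NHS (-4.19 ± 0.22), GPR39 (-4.14 ± 0.35), ZHX2 (-4.06 ± 0.13) and DNAJC6 (-4.01 ± 0.28). Further falls were in ARHGAP42 (-3.77 ± 0.29), TRPS1 (11.9-fold lower, -3.57 ± 0.14), SH3RF1 (-3.48 ± 0.17), ZSWIM6 (-3.47 ± 0.33), FGD4 (-3.47 ± 0.20) and ZCCHC7 (-3.45 ± 0.12). Of 17746 genes tested 1316 were higher and 2867 lower, 23.6%, and with a fold minimum of 2, 237 and 1147.

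In MCF7 the list-wise picture with SKBG-1 (R) was led by NRF2 targets, of which 21 of 23 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 3.16e-25). Cholesterol synthesis had 16 of 20 higher and 0 lower by both counts (camera adjusted p = 6.8e-13), MSMO1 at 1.31, LDLR at 1.12, INSIG1 at 1.12 and STARD4 at 0.98. DBHS and paraspeckle genes had 7 of 14 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 1.81e-06), with the paraspeckle RNA NEAT1 at 0.98 and CPSF6 at 0.88. Lineage factors had 10 of 18 lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 5.46e-07), with AR at -1.13 ± 0.10 and SOX9 at -0.91. Breast line markers had 4 of 12 lower and 1 higher by both counts (camera adjusted p = 0.000604), with the prolactin receptor gene PRLR at -1.98, although their median was 0.01. Those 5 lists kept their call with an estimated correlation. Lost with it were the unfolded protein response (11 of 18 higher, 12 adjusted over the list alone; camera adjusted p = 1.51e-06; adjusted p = 0.0597 with an estimated correlation) and ATF4 targets (10 of 24 higher, 11 adjusted over the list alone; 0.000696; adjusted p = 0.0597 with an estimated correlation). So were heat shock genes (7 of 20 higher, 9 adjusted over the list alone; 0.00351; adjusted p = 0.263 with an estimated correlation) and immediate early genes (11 of 26 higher and 2 lower, 12 and 2 adjusted over the list alone; 0.000543; adjusted p = 0.23 with an estimated correlation). Likewise lost were prostate line markers (4 of 7 lower by both counts; 0.0459; adjusted p = 0.105 with an estimated correlation) and MYC targets in ribosome biogenesis (2 of 24 higher, 1 adjusted over the list alone; 0.0459; adjusted p = 0.441 with an estimated correlation).

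The estrogen response list in MCF7 had 3 of 31 genes higher and 8 lower (3 and 9 adjusted over the list alone; camera adjusted p = 1), with the corepressor gene NRIP1 at -1.06, ADCY9 at -0.79, MYB at -0.66 and EGR3 at 0.62. Splicing factors had 4 of 31 higher and 10 lower (4 and 11 adjusted over the list alone; camera adjusted p = 0.407), with SRSF4 at -1.85 ± 0.12, TRA2B at -1.24, TRA2A at -0.80 and HNRNPH1 at 0.51. Androgen response genes had 1 of 22 higher and 8 lower (1 and 9 adjusted over the list alone; camera adjusted p = 0.0858). Also not called were p53 targets (4 of 25 higher, 4 lower; 5 and 5 adjusted over the list alone; camera adjusted p = 0.334), NF-kB targets (3 of 13 lower, adjusted p = 0.393) and interferon-stimulated genes (1 of 17 lower, adjusted p = 0.924). Nor were hypoxia targets (4 of 20 higher, 2 lower, adjusted p = 0.27), S phase (1 of 28 higher, 2 lower, adjusted p = 0.155) and G2 and mitosis genes (1 of 26 lower, adjusted p = 0.376). The rest were DNA repair genes (1 of 26 higher, 2 lower; 0 and 0 adjusted over the list alone; camera adjusted p = 0.341), histones (1 of 12 higher, adjusted p = 0.114), mitochondrially encoded mRNAs (0 of 13 called by edgeR with either adjustment; median 0.52, adjusted p = 0.0974) and fibroblast and blood cell markers (0 of 10 with either, adjusted p = 0.82). Genes changed by SKBG-1 (R) in both lines went mostly the same way. Of 15992 genes tested in each, 2209 were lower in both against 743 for independent lists. Higher in both were 871 against 342, and 97 were called in opposite directions. The fold changes correlated across genes, which are not independent replicates, at r = 0.56 and rho = 0.58.

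**Figure D1:**
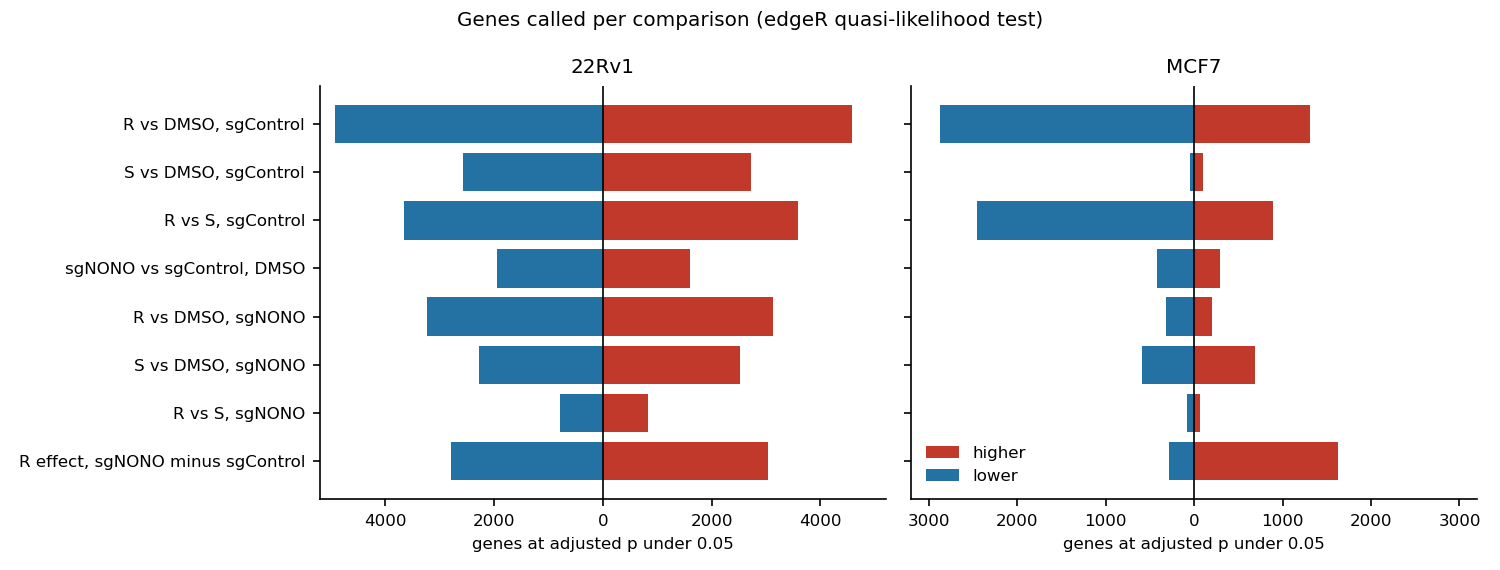
Number of genes called higher and lower in each comparison of 22Rv1 and MCF7, from edgeR with Benjamini-Hochberg adjustment. SKBG-1 (R) in sgControl cells gave 4576 higher and 4922 lower genes in 22Rv1 and 1316 and 2867 in MCF7.

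SKBG-1 (S), the stereoisomer at the same dose and time, raised stress genes in sgControl 22Rv1 cells as well. HMOX1 rose 113-fold (6.82 ± 0.19), CHAC1 by 4.69 ± 0.17, HSPA6 by 4.20 ± 0.30, OSGIN1 by 4.15 ± 0.06 and HSPA1A by 4.03 ± 0.22. SFPQ (0.17 ± 0.04) and PSPC1 (0.17 ± 0.04) rose slightly and MYC fell by 0.47 ± 0.05. AR was higher by 0.09 ± 0.03 (edgeR adjusted p = 0.0346). That call was lost without sgControl DMSO replicate 1 (0.07, edgeR adjusted p = 0.137) or 2 (0.09, 0.0869) and without SKBG-1 (S) replicate 1 (0.09, 0.0554) or 3 (0.07, 0.132). It was also lost with no expression filter (0.11, 0.0695) and with only the groups compared in the fit (0.09, 0.101). NONO was higher by 0.11 (edgeR adjusted p = 0.045), which was lost in each of the 6 fits that left out 1 library, at values of 0.09 to 0.13. In total 2726 genes were higher and 2563 lower, of which 144 and 473 by at least 2-fold. The largest falls were in IRAG2 (0 counts with SKBG-1 (S), at least 160-fold lower), TACSTD2 (-4.90 ± 1.2), PLAU (-4.69 ± 1.2), NEB (-4.57 ± 1.5) and ALDH1A3 (-3.92 ± 0.89). NEB moved to -7.12 without SKBG-1 (S) replicate 2 and lost its call without replicate 1 (-4.04, edgeR adjusted p = 0.0796) or 3 (-4.11, 0.0895). It belongs to the 18 genes of the third pattern below, whose reads may come from other samples. TACSTD2, PLAU and ALDH1A3 are outside that set but had standard errors of 0.89 to 1.2, against 0.06 to 0.30 for the rises named here. IRAG2, also outside it, held 5.91 CPM with DMSO and 2.99 CPM with SKBG-1 (R) in sgControl cells. Whether reads from other samples contribute to these falls was not tested.

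By list, SKBG-1 (S) in sgControl 22Rv1 raised 15 of 23 NRF2 targets (16 adjusted over the list alone; camera adjusted p = 4.26e-79), 22 of 24 ATF4 targets (22 alone, camera adjusted p = 1.65e-89), 19 of 20 heat shock genes (19 alone, camera adjusted p = 5.14e-39) and 15 of 21 cholesterol synthesis genes (16 alone, camera adjusted p = 6.31e-22). No member of these lists was lower. G2 and mitosis genes fell in 19 of 26 cases (21 adjusted over the list alone; camera adjusted p = 1.61e-10), by small amounts such as -0.53 for MKI67, -0.47 for PLK1 and -0.46 for KIF20A. MYC targets in ribosome biogenesis had 16 of 24 higher and 2 lower (17 and 2 adjusted over the list alone; camera adjusted p = 0.000479). Splicing factors had 13 of 31 higher and 1 lower (16 and 3 alone, adjusted p = 4.79e-05). Among the latter SRSF5 was at 0.44 and RBM39 at 0.42. p53 targets had 10 of 25 higher and 5 lower (10 and 6 alone, camera adjusted p = 2.71e-05). Those 8 lists held with an estimated correlation. The unfolded protein response (10 of 18 higher, 11 adjusted over the list alone, adjusted p = 2.99e-08) lost its call, adjusted p = 0.0857 with an estimated correlation. So did prostate line markers (1 of 12 higher, 5 lower; 2 and 7 alone; 5.23e-05; adjusted p = 0.0822 with an estimated correlation) and androgen response genes (3 of 24 higher, 9 lower; 5 and 11 alone; 0.00487; adjusted p = 0.0822 with an estimated correlation).

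In MCF7, SKBG-1 (S) changed fewer genes, 101 higher and 50 lower, of which 22 and 3 by at least 2-fold. HMOX1 rose 8.88-fold (3.15 ± 0.17), OSGIN1 by 2.14 ± 0.12, BHLHA15 by 1.94 ± 0.16, the cystine transporter gene SLC7A11 by 1.82 ± 0.14 and DNAJB9 by 1.34 ± 0.12. ESR1 (-0.15 ± 0.09, edgeR adjusted p = 0.56), NONO (-0.10), SFPQ (0.04), PSPC1 (0.03) and MYC (-0.06) were not called. NRF2 targets had 13 of 23 higher (17 adjusted over the list alone; camera adjusted p = 5.76e-81), the unfolded protein response 5 of 18 (12 alone, camera adjusted p = 9.36e-24), ATF4 targets 3 of 24 (8 alone, camera adjusted p = 6.87e-12) and cholesterol synthesis 5 of 20 (9 alone, camera adjusted p = 4.69e-11), with 0 lower in each. NF-kB targets had 3 of 13 lower (8 lower and 1 higher alone, adjusted p = 6.84e-09). Lineage factors had 0 of 18 higher and 1 lower (0 and 3 alone, camera adjusted p = 4.9e-06). All 6 were called with an estimated correlation too. Mitochondrially encoded mRNAs had 0 of 13 called by edgeR with either adjustment and a median of 0.87 (camera adjusted p = 1.08e-07; adjusted p = 0.317 with an estimated correlation). The NF-kB feedback gene TNFAIP3 (-1.06 ± 0.19) lost its call without DMSO replicate 3 (-0.99, edgeR adjusted p = 0.0605), SKBG-1 (S) replicate 1 (-0.99, 0.0717) or 2 (-1.04, 0.0599), and SYNPO2 (-0.93) without SKBG-1 (S) replicate 1 (-0.82, 0.0686). The count of 151 genes was 65 to 91 when any 1 library was left out, lowest without SKBG-1 (S) replicate 1 and highest without DMSO replicate 2. It was 797 (468 higher) with only the 2 groups in the fit, 417 (298 higher) with no expression filter and 344 (201 higher) by DESeq2.

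Set against each other in sgControl cells, the 2 stereoisomers differed in the long genes, in AR or ESR1 and in the DBHS genes. In 22Rv1, SKBG-1 (R) left ZSWIM6 13-fold lower than SKBG-1 (S) did (-3.70 ± 0.16), LIN52 at -3.47 ± 0.10, ZHX2 at -3.38 ± 0.13, BTRC at -3.35 ± 0.15, FAM110B at -3.33 ± 0.07 and AR 2.36-fold lower (-1.24 ± 0.03). Higher with SKBG-1 (R) were SFPQ (0.81 ± 0.04), PSPC1 (0.50 ± 0.04), NONO (0.14), MYC (0.20 ± 0.05) and ZNF587B (2.18 ± 0.09), and so were TTC6 (1.42 ± 0.15), TMPPE (1.38 ± 0.13) and TXNDC11 (1.17 ± 0.05), of which ZNF587B and TMPPE overlap other annotated genes. SFT2D3 had 534 counts with SKBG-1 (R) and 2 with SKBG-1 (S), a ratio of 278 per total count with a 95% counting interval of 76.5 to 2300. In total 3591 genes were higher and 3653 lower, 119 and 1062 by at least 2-fold. In MCF7 the same comparison gave 893 higher and 2457 lower genes. BTRC was 19.8-fold lower (-4.31 ± 0.14), with GPR39 at -4.12 ± 0.35, PDZRN3 at -4.08 ± 0.22, ZSWIM6 at -3.87 ± 0.32, ZHX2 at -3.87 ± 0.13 and ESR1 2.59-fold lower (-1.37 ± 0.09). Higher in MCF7 were PSPC1 (1.56 ± 0.09), SFPQ (0.75 ± 0.07), MYC (0.61 ± 0.13), IGF2 (2.39 ± 0.25), FSBP (1.61 ± 0.14) and RBMXL1 (1.41 ± 0.11). MCF7 NONO was 0.29 higher (edgeR adjusted p = 0.0376), which was lost without SKBG-1 (R) replicate 1 (0.28, 0.101) or 2 (0.26, 0.118) and without any SKBG-1 (S) replicate (0.28, 0.29 and 0.30, with 0.108, 0.101 and 0.083).

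Lists were also compared between the stereoisomers in sgControl cells. In 22Rv1, NRF2 targets (9 of 23 higher with SKBG-1 (R), 6 lower; 10 and 6 adjusted over the list alone; camera adjusted p = 0.776), heat shock genes (4 of 20 higher, 1 lower, adjusted p = 0.526) and ATF4 targets (7 of 24 higher, 2 lower, adjusted p = 0.545) were not called as lists. HMOX1 differed between them by -0.08 ± 0.13 (edgeR adjusted p = 0.66) and HSPA6 by 0.09 ± 0.20 (0.777), which does not show that the stereoisomers act alike on them. SLC7A11 was lower with SKBG-1 (R) by 1.40 ± 0.08 on the log2 scale (log2 fold change -1.40). Called were DBHS genes (8 of 14 higher, 2 lower; 11 and 2 adjusted over the list alone; camera adjusted p = 9.14e-08), cholesterol synthesis (19 of 21 higher, 19 alone, adjusted p = 2.28e-15), G2 and mitosis (17 of 26 higher, 17 alone, adjusted p = 0.000151) and lineage factors (2 of 17 higher, 7 lower, the same alone, adjusted p = 0.000266), each with an estimated correlation too. The unfolded protein response (17 of 18 higher, 17 adjusted over the list alone, adjusted p = 3.37e-11) had adjusted p = 0.07 with an estimated correlation. In the splicing factor list SRSF4 was lower by 2.66 ± 0.05 (log2 fold change -2.66), TRA2B at -0.96 and SRSF5 at -0.71. In MCF7, DBHS genes (8 of 14 higher, 1 lower; 9 and 1 adjusted over the list alone; camera adjusted p = 8.11e-08) and breast line markers (5 of 12 lower, 5 alone, adjusted p = 0.000372) held with an estimated correlation. NRF2 targets in MCF7 (8 of 23 higher, 2 lower; 15 and 2 adjusted over the list alone, adjusted p = 0.00298), with HMOX1 0.94 ± 0.15 higher with SKBG-1 (R), had adjusted p = 0.324 with an estimated correlation, and cholesterol synthesis (13 of 20 higher, 17 alone, adjusted p = 2.73e-06) adjusted p = 0.142 with an estimated correlation.

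Fold changes with SKBG-1 (R) and SKBG-1 (S) against the same DMSO libraries correlated across genes at r = 0.52 in 22Rv1 and 0.46 in MCF7, where unchanged groups simulated against those libraries gave 0.49 and 0.52. Their covariance was 0.254 in 22Rv1 against 0.0514 simulated and 0.183 in MCF7 against 0.0791. In 22Rv1, 1882 genes were higher and 1736 lower with each, against 684 and 692 for independent lists. The DMSO libraries were shared between these comparisons.

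Differences between the guides without compound were read from sgNONO against sgControl cells in DMSO. They cannot be put on the loss of NONO alone, since a guide cannot be separated from a single clone or pool. In 22Rv1 the partner genes were higher, PSPC1 2.11-fold (1.08 ± 0.04) and SFPQ 1.5-fold (0.59 ± 0.04), as were the clock repressor gene BHLHE41 (1.67 ± 0.08), the hormone subunit gene CGA (1.47 ± 0.10), SSPN (1.42 ± 0.13) and TRGC1 (1.35 ± 0.04). BHLHE41 and SSPN overlap on opposite strands. AR (0.02) and MYC (0.00) were not called. NEAT1 was lower by 0.88 ± 0.10 (log2 fold change -0.88), the luminal factor gene GATA3 by 1.45 (-1.45) and SRSF4 by 0.40 (-0.40). Of 18231 genes 1605 were higher and 1950 lower, 64 and 469 by at least 2-fold. SPP1 (-5.45), ABCC3 (-4.75 ± 1.0), C3 (-4.74), NEB and IRAG2 were the largest falls among named genes. NEB is in the third pattern below, whose reads may come from other samples (untested for the other falls). It stood at 7.63, 8.88 and 9.04 CPM in sgControl DMSO, but at 0, 0.0383 and 11.1 CPM in sgControl SKBG-1 (R). The call of NEB was lost without sgNONO DMSO replicate 1, 2 or 3 (edgeR adjusted p = 0.0507, 0.0598 and 0.0525), as was that of IRAG2 (0.0643, 0.0783 and 0.0656). The unfolded protein response had 15 of 18 genes lower, 15 adjusted over the list alone (camera adjusted p = 8.84e-13; adjusted p = 0.105 with an estimated correlation). Immediate early genes had 10 of 27 lower and 1 higher (11 and 1 alone; 0.000519; adjusted p = 0.114 with an estimated correlation). CCN1 was at -2.15, FOSL1 at -2.13, FOSB at -1.74 and FOS at -1.02.

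In MCF7, sgNONO cells had SFPQ higher by 0.65 ± 0.07 and PSPC1 by 1.07 ± 0.09, with ESR1 (0.03) and MYC (-0.14) not called. Higher too were the thyroid hormone deiodinase gene DIO2 (2.63 ± 0.18), the fibrillin gene FBN2 (1.42 ± 0.20), COL5A2 (1.32 ± 0.16), GLRA3 (1.31 ± 0.18) and TNFRSF11B (1.27 ± 0.23). The anti-apoptotic gene BCL2 was 12-fold lower (-3.59 ± 0.12), and AGBL1 (-3.55 ± 0.25), SGCG (-2.74 ± 0.21), TENM3 (-2.66 ± 0.21) and SLC26A2 (-2.23 ± 0.16) fell. Of 17746 genes 289 were higher and 417 lower, 52 and 111 by at least 2-fold. Within the estrogen response list, PDZK1 (-1.54), HSPB8 (-1.30) and PGR (-0.79) were lower and AREG (0.82) higher, and the list was not called (3 of 31 higher, 5 lower; 5 and 7 adjusted over the list alone; camera adjusted p = 0.228). p53 targets were called (8 of 25 higher, 1 lower, the same adjusted over the list alone; camera adjusted p = 3.99e-05, 0.0129 with an estimated correlation), with GDF15 at 0.98, FAS at 0.59 and TP53I3 at -0.72. The count of 706 genes fell to 319 without sgControl DMSO replicate 1 and was 806 without sgNONO DMSO replicate 2. It was 141 (45 higher, 96 lower) with only the 2 groups in the fit, 1325 (822 higher, 503 lower) with no expression filter and 1147 (541 higher, 606 lower) by DESeq2. The sgNONO effects of both lines correlated across genes at r = 0.05.

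SKBG-1 (R) was then compared with DMSO within sgNONO cells. In 22Rv1 the stress genes rose there too, HMOX1 89.5-fold (6.48 ± 0.18), CHAC1 by 5.76 ± 0.16, DDIT4 by 4.41, DDIT3 by 4.27 and HSPA1A by 4.18 ± 0.22. AR rose by 0.21 ± 0.03, SFPQ fell by 0.14 ± 0.04, MYC fell by 0.54 ± 0.05, the remaining NONO transcript rose by 0.58 ± 0.05 and PSPC1 was not called (0.01). The largest falls were in the iron exporter gene SLC40A1 (4.77-fold lower, -2.25 ± 0.11), TRAM1L1 (-1.81), SLITRK5 (-1.74), PEX11A (-1.70) and HOXA5 (-1.67), which lies in an intron of HOXA3. Of all genes 3121 were higher and 3225 lower, 274 and 399 by at least 2-fold. ATF4 targets had 23 of 24 higher (23 adjusted over the list alone; camera adjusted p = 7.64e-106), NRF2 targets 16 of 23 (16 alone, camera adjusted p = 1.58e-61), heat shock genes 16 of 20 (16 alone, camera adjusted p = 2.43e-26), the unfolded protein response 16 of 18 (17 alone, camera adjusted p = 1.09e-22) and cholesterol synthesis 17 of 21 (17 alone, camera adjusted p = 2.59e-34), with 0 lower in each. G2 and mitosis genes had 17 of 26 lower (18 alone, camera adjusted p = 1.81e-07). Immediate early genes had 19 of 27 higher and 3 lower (22 and 3 alone, camera adjusted p = 1.07e-19), and lineage factors 4 of 17 higher and 7 lower (4 and 8 alone, camera adjusted p = 0.00264). These 8 lists held with an estimated correlation, at adjusted p = 0.000269 for immediate early genes and 0.0306 for lineage factors by camera. So did p53 targets (11 of 25 higher, 5 lower; 11 and 6 alone; camera adjusted p = 3.29e-06), estrogen response genes (9 of 27 higher, 5 lower; 11 and 6 alone; camera adjusted p = 0.00241), MYC targets in ribosome biogenesis (17 of 24 higher, 2 lower; 19 and 2 alone; camera adjusted p = 4.45e-06) and splicing factors (15 of 31 higher, 3 lower; 15 and 4 alone; camera adjusted p = 1.79e-05). DBHS genes were not called (7 of 14 higher, 3 lower; 7 and 4 alone, adjusted p = 0.222).

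In MCF7 sgNONO cells, SKBG-1 (R) raised HMOX1 22.2-fold (4.47 ± 0.18), OSGIN1 by 2.89, SLC7A11 by 1.92, AKR1B10 by 1.78 and FOSL1 by 1.76, and lowered the G protein regulator gene RGS16 (-1.19 ± 0.14). ESR1 (-0.12 ± 0.09, edgeR adjusted p = 0.537), NONO (0.16), SFPQ (-0.02), PSPC1 (0.05) and MYC (0.49, 0.052) were not called. NRF2 targets had 19 of 23 higher (21 adjusted over the list alone; camera adjusted p = 5.08e-125), cholesterol synthesis 10 of 20 (13 alone, camera adjusted p = 1.52e-26) and ATF4 targets 8 of 24 (14 higher and 1 lower alone, adjusted p = 1.6e-10), each held with an estimated correlation. Mitochondrially encoded mRNAs had 0 of 13 called by edgeR with either adjustment and a median of 0.75 (camera adjusted p = 2.43e-06; adjusted p = 0.31 with an estimated correlation). Between replicates, the chi-square per gene was 137 to 260 in sgNONO DMSO and 20.1 to 179 in sgNONO SKBG-1 (R), against 6.72 to 10 in sgControl DMSO. In all, 204 genes were higher and 312 lower. The total of 516 fell to 250 without SKBG-1 (R) replicate 2 and to 51 with only the 2 groups in the fit, and was 1089 with no expression filter and 805 by DESeq2. Among falls, FOXO6 (-1.13) lost its call in that smaller fit (edgeR adjusted p = 0.11). CITED4 (-1.14) lost its call without sgNONO DMSO replicate 2 (-0.58, 0.0918) or SKBG-1 (R) replicate 1, 2 or 3 (0.124, 0.118 and 0.0642). KCNJ8 (-1.11) lost it without SKBG-1 (R) replicate 1 (-0.97, 0.0992) or 2 (-0.97, 0.0891).

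The interaction, the SKBG-1 (R) effect in sgNONO cells minus that in sgControl cells, tested whether the response depended on the guide. In 22Rv1 it was 1.36 ± 0.05 for AR, -1.13 ± 0.05 for SFPQ, -0.67 ± 0.05 for PSPC1, 0.32 ± 0.07 for NONO and -0.26 ± 0.07 for MYC. TRPS1 (3.0 ± 0.12), SRSF4 (3.01 ± 0.06) and TRA2B (1.19 ± 0.09) had smaller falls or rises in their place in sgNONO cells, and ZNF587B (-2.40 ± 0.13), TTC6 (-1.33), HOXA7 (-1.31) and C2orf27A (-1.30) had negative values. In MCF7 it was 1.40 ± 0.13 for ESR1, -0.82 ± 0.09 for SFPQ, -1.54 ± 0.12 for PSPC1, 4.15 ± 0.17 for BTRC, 4.11 ± 0.41 for ZSWIM6, 3.31 ± 0.18 for TRPS1, 2.02 ± 0.16 for SRSF4 and 1.41 ± 0.12 for TRA2B. It was not called for NONO (-0.02) or MYC (-0.06). TGFB2-OT1, which overlaps TGFB2 in the annotation, had 0 counts with SKBG-1 (R) in MCF7 sgControl cells, at least 88.8-fold lower than with DMSO, and 3.82 ± 0.480 CPM in sgNONO cells. The interaction was called for 3034 genes upward and 2789 downward in 22Rv1 and for 1623 and 288 in MCF7. By size, 1218 genes in 22Rv1 and 874 in MCF7 had an interaction of at least 1 on the log2 scale upward, against 109 and 79 downward. Genes called with SKBG-1 (R) in both backgrounds of 22Rv1 were 2000 higher and 1880 lower, against 783 and 871 for independent lists, with 675 in opposite directions.

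SKBG-1 (S) against DMSO in sgNONO 22Rv1 cells raised HMOX1 by 6.37 ± 0.18, CHAC1 by 4.97, HSPA1A by 4.17, OSGIN1 by 3.98 and DDIT4 by 3.63, and lowered SLC40A1 (-1.66 ± 0.10), SLITRK5 (-1.49), MAFB (-1.29), PRR15L (-1.28) and GPR37 (-1.27). AR rose by 0.16 ± 0.03, NONO by 0.22 and MYC fell by 0.51, with SFPQ (-0.08) and PSPC1 (-0.04) not called. ATF4 targets had 23 of 24 higher (camera adjusted p = 8.12e-110), heat shock genes 17 of 20 (18 adjusted over the list alone, adjusted p = 5.08e-37), and G2 and mitosis genes 22 of 26 lower (24 alone, camera adjusted p = 6.38e-15), each with an estimated correlation too. In total 2518 genes were higher and 2264 lower. In MCF7 sgNONO cells 692 genes were higher and 592 lower, led by HMOX1 (3.53 ± 0.17), OSGIN1 (2.30) and SLC7A11 (1.74). ESR1 was lower by 0.43 ± 0.09 (log2 fold change -0.43, edgeR adjusted p = 0.0106), lost without SKBG-1 (S) replicate 1 (-0.32, 0.0554). SFPQ was lower by 0.24 (-0.24, 0.0341), lost without DMSO replicate 1 (-0.27, 0.0508) or SKBG-1 (S) replicate 1 (-0.21, 0.137) or 3 (-0.24, 0.0914). The count of 1284 ran from 310 without SKBG-1 (S) replicate 1 to 2060 without sgNONO DMSO replicate 2 and was 8 with only the 2 groups in the fit, 1919 with no expression filter and 1935 by DESeq2. Mitochondrially encoded mRNAs had 9 of 13 higher, all 13 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 1.74e-14; adjusted p = 0.127 with an estimated correlation). Here 1 of the DMSO libraries had the mitochondrial share of 1.02% given above.

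Between the stereoisomers in sgNONO cells of 22Rv1, 835 genes were higher and 788 lower with SKBG-1 (R), 13 and 32 by at least 2-fold. The 5 rises named by the rule were HERPUD1 (1.06 ± 0.08), BHLHA15 (1.05 ± 0.05), DDIT3 (1.0 ± 0.14), DNAJB9 (0.94 ± 0.09) and HSPA5 (0.84 ± 0.06). The 5 falls were MT1F (-1.54 ± 0.08), MT1G (-1.36 ± 0.11), SLC30A2 (-1.33 ± 0.19), MT1X (-1.20 ± 0.10) and MT1E (-1.05 ± 0.09). The metallothionein genes (MT1) are close paralogs, whose reads may be shared. AR differed by 0.05 (edgeR adjusted p = 0.356) and NONO by 0.36 ± 0.05. The unfolded protein response had 15 of 18 higher (17 adjusted over the list alone; camera adjusted p = 9.77e-40) and cholesterol synthesis 16 of 21 (17 alone, camera adjusted p = 1e-53), with an estimated correlation too. The count of 1623 was 851 without SKBG-1 (R) replicate 2. In MCF7 sgNONO cells 66 genes were higher and 76 lower, among them EGR3 (0.80 ± 0.10) and LPIN1 (0.76 ± 0.10) higher and the zinc transporter gene SLC30A1 (-0.90 ± 0.09) lower, with ESR1 at 0.30 ± 0.09 (edgeR adjusted p = 0.0948). That count of 142 was 3 without SKBG-1 (S) replicate 3, 448 without SKBG-1 (S) replicate 2 and 7 with only the 2 groups in the fit. It was 29 with a replicate block, 845 with no expression filter, 844 by DESeq2 and 483 among genes of at least 5 CPM.

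The span of a gene on the chromosome went with its response to SKBG-1 (R) in sgControl cells. Over 17949 genes of 22Rv1 the rank correlation of span and log2 fold change was -0.30, and over 17445 genes of MCF7 -0.37, across genes, which are not independent replicates. Among 1259 genes of 200 kb or more in 22Rv1 786 (62.4%) were lower and 45 higher, with a median of -0.63. In MCF7 647 of 1174 (55.1%) were lower and 21 higher, with a median of -0.65. Genes under 10 kb had medians of 0.09 and 0.15. In sgNONO cells the correlation was 0.01 in 22Rv1 and -0.02 in MCF7, with medians of -0.03 and -0.05 for the long genes. The MCF7 value was -0.18 without sgNONO DMSO replicate 2 and 0.05 without replicate 3. With SKBG-1 (S) in sgControl cells it was -0.03 and -0.15, with medians of -0.07 and -0.07, and MCF7 ran from -0.21 without SKBG-1 (S) replicate 2 to -0.09 without replicate 1. With SKBG-1 (S) in sgNONO cells it was 0.07 in 22Rv1 and -0.17 in MCF7, where it ran from -0.28 without sgNONO DMSO replicate 2 to -0.08 without SKBG-1 (S) replicate 1. For the interaction of SKBG-1 (R) with the guide it was 0.33 and 0.36.

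Splicing was available for 22Rv1 from the authors' deposited table of each of 6 comparisons. With SKBG-1 (R) in sgControl cells 1749 of 97400 covered events in 1134 genes passed, 1406 (80.4%) with higher and 343 with lower inclusion than with DMSO. Of 1419 skipped-exon events 1212 had higher inclusion. Retained introns had 14 higher and 27 lower, and mutually exclusive exons 136 and 79. In the authors' deposited table an 87-base exon of CMC2 (chromosome 16 81001248 to 81001334) went from 16.4% to 89.6% inclusion, one of PPM1A (chromosome 14 60277005 to 60277091) from 19.2% to 86.2%, and one of NRF1, a regulator of mitochondrial biogenesis (chromosome 7 129630078 to 129630168), from 3.5% to 67%. An exon of the DNA repair gene RAD54B (chromosome 8 94432611 to 94432656) went from 5.3% to 68.8% and one of the methyltransferase gene KMT2E (chromosome 7 105038126 to 105038199) from 27.4% to 87.8%. With SKBG-1 (S) the PPM1A exon stood at 10.7% and the NRF1 exon at 4.57%, and with SKBG-1 (R) in sgNONO cells at 21.2% and 7.97%. The CMC2 exon stood at 24.2% with SKBG-1 (S), and at 52.4% in sgNONO cells with DMSO against 16.4% in sgControl cells (limma with precision weights, adjusted p = 3.23e-19) in the authors' deposited table. On the ratios between libraries limma called 21 events without weights and 830 with precision weights, chosen after the data were seen. Unweighted limma called 0% of simulated differences of 20 points, so its lower count does not show that the authors' rates ignore the spread between libraries.

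In the other comparisons of the authors' deposited tables, SKBG-1 (S) against DMSO in sgControl cells gave 528 events, 211 higher and 317 lower, with retained introns of CIRBP (25.9% against 66.1%), SELENBP1 (40.2% against 74.6%) and RACK1 (35.4% against 69.5%) lower with SKBG-1 (S). SKBG-1 (R) against DMSO in sgNONO cells gave 1012 events, 329 higher and 683 lower, among them AUP1 (48.8% against 97.4%), ZCCHC8 (48.5% against 92.8%), NECAP1 (51.4% against 94.6%) and TIRAP (37.8% against 79.6%). The sgControl against sgNONO comparison in DMSO gave 409 events, 158 higher and 251 lower in sgControl, with an exon of the adhesion receptor gene CD44 (chromosome 11 35206112 to 35206243) at 66.6% against 23.2%, RANBP3 at 47.2% against 83.8% and PPFIBP1 at 82% against 48.2%. With SKBG-1 (R), sgControl against sgNONO cells differed in 2283 events, 1890 higher in sgControl. SKBG-1 (R) against SKBG-1 (S) in sgControl cells differed in 1919 events, 1587 higher with SKBG-1 (R). An exon of EZH2, a histone methyltransferase gene (chromosome 7 148836822 to 148837000), was included at 81.2% with SKBG-1 (R) in sgControl cells against 4.43% in sgNONO cells and 4.47% with SKBG-1 (S), at means of 21, 40.7 and 50.7 reads. ERBIN (90.6% against 28.7%) and SLC25A36 (82.2% against 22.3%) were further examples.

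In the order SKBG-1 (S), SKBG-1 (R) in sgNONO, guides in DMSO, guides with SKBG-1 (R) and stereoisomers, limma on the ratios between libraries called 0, 0, 0, 7 and 1 events without weights and 100, 351, 79, 1209 and 914 with precision weights. Of the events named from these tables, limma with precision weights did not call CIRBP (adjusted p = 0.172), SELENBP1 with SKBG-1 (S) (adjusted p = 0.285), RANBP3 (adjusted p = 0.0708) or AUP1 (adjusted p = 0.0682). It called PPFIBP1 (adjusted p = 0.043), TIRAP (adjusted p = 0.0499) and NECAP1 (adjusted p = 0.00928), whose highest limma adjusted p with 1 library left out were 0.377, 0.26 and 0.089. RACK1 (limma adjusted p = 0.000332), ZCCHC8 (0.000193), CD44 (1.08e-06) and ERBIN (0.000528) were called, also with any 1 library left out. Without weights limma called CMC2, NRF1 and RAD54B among the named events with SKBG-1 (R) against DMSO in sgControl cells, and 0 of those named for the comparisons in the preceding paragraph.

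Of the 1406 events with higher inclusion under SKBG-1 (R) in sgControl cells, 1208 were covered in the sgNONO table of SKBG-1 (R) against DMSO, where 34 passed as higher and 40 as lower and the median difference was -0.6 points against 18.8 points in sgControl cells. In the table of SKBG-1 (S), 57 of 1287 passed as higher and 2 as lower, with a median of 1.9 points. In the direct comparison with SKBG-1 (S), 826 of 1274 passed as higher and 0 as lower in the authors' deposited table, with a median of 16.4 points, and against sgNONO cells with SKBG-1 (R) 748 of 1268 passed as higher and 1 as lower. Of 1276 covered in the DMSO comparison of guides, 80 were lower in sgControl than in sgNONO cells and 1 was higher, with a median of -4.5 points. These tables share libraries, so the counts are not independent of each other.

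**Figure D2:**
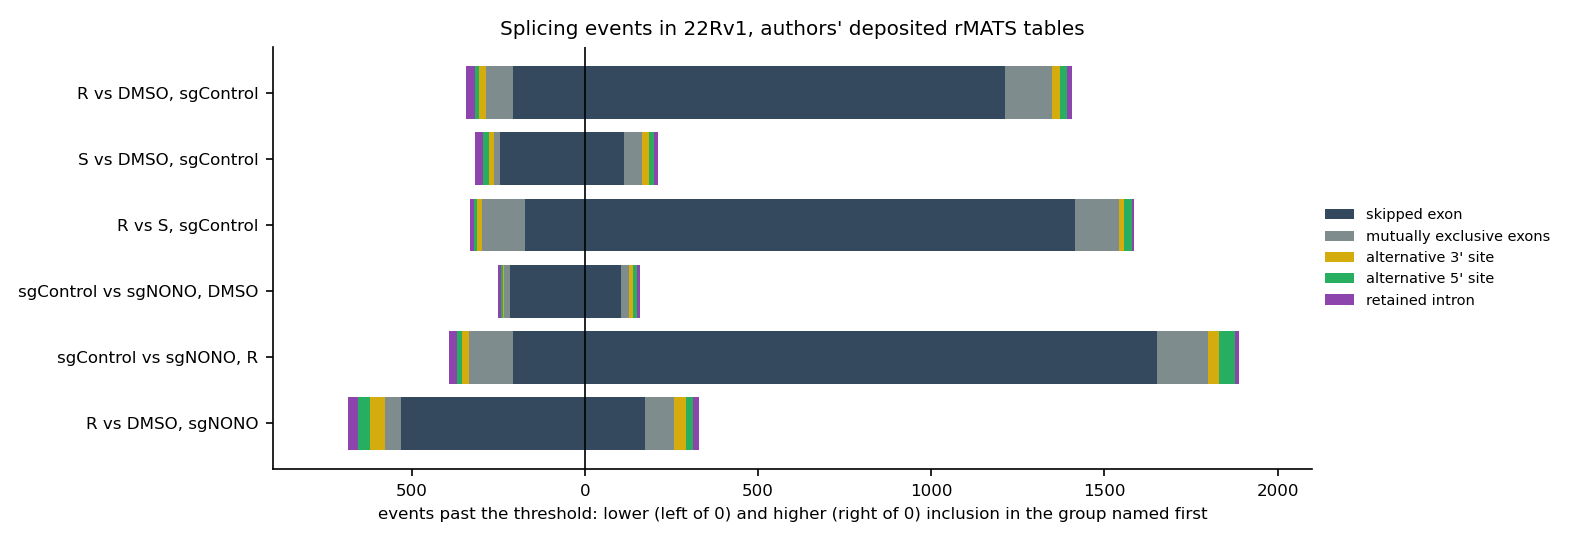
Number of splicing events past the threshold with higher and lower inclusion in the first group of each of the 6 comparisons in 22Rv1, by event type, from the authors' deposited tables. SKBG-1 (R) against DMSO in sgControl cells gave 1406 events with higher and 343 with lower inclusion.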

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

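Of the tests in this part, those of reads from other samples and of treatment or guide in the third pattern, of a length bias of 1 library, of the NONO need of the difference between single-exon genes, and the redraws of the guide and of residuals were chosen after the result was seen.

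The effect of SKBG-1 (R) differed between sgNONO and sgControl cells, by the interaction test, for 5823 genes in 22Rv1 and 1911 in MCF7. In 22Rv1, 3 of the 12 largest rises and 10 of the 12 largest falls differed. The interaction was 0.85 for CHAC1, 0.74 for DDIT4, 0.44 for SESN2, 4.73 for IGFBP7, 4.90 for TGFBI, 3.85 for ZSWIM6, 2.94 for BTRC, 2.97 for ZHX2, 3.06 for FAM110B, 3.11 for ZNRF3, 2.33 for KCNJ3, 3.21 for E2F3 and 3.48 for LIN52. NONO (0.32), SFPQ (-1.13), PSPC1 (-0.67), MYC (-0.26) and AR (1.36) differed as well. The call of CHAC1 held without sgControl SKBG-1 (R) replicate 1 (0.73, edgeR adjusted p = 0.0494) or 3 (1.0, 0.0114) and without sgNONO SKBG-1 (R) replicate 3 (0.92, 0.0344), and was lost when any library other than these was left out, at 0.68 to 0.93, and with RLE size factors (0.85, 0.0501) or a replicate block (0.86, 0.054). That of SESN2 was lost without sgControl DMSO replicate 1 (0.44, edgeR adjusted p = 0.0515) or 2 (0.41, 0.0698), sgControl SKBG-1 (R) replicate 1 (0.37, 0.0604), sgNONO DMSO replicate 1 (0.43, 0.0579) or 2 (0.43, 0.0593) and sgNONO SKBG-1 (R) replicate 1 (0.41, 0.0556). IGFBP7 kept its call without sgControl DMSO replicate 3 (4.77, edgeR adjusted p = 0.049), sgControl SKBG-1 (R) replicate 2 (5.26, 0.0461) or sgNONO SKBG-1 (R) replicate 1 (5.00, 0.0495), and lost it when any library other than these was left out.

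In MCF7, 8 of the 12 largest rises and all 12 of the largest falls named in the report differed between the guides. The interaction was -1.10 for BHLHA15, -1.93 for IGF2, -1.08 for DNAJB9, -1.54 for PSPC1, -1.41 for TTC32, -1.41 for FSBP and -1.17 for CUTC. It was 4.15 for BTRC, 3.24 for PDZRN3, 3.46 for NHS, 3.28 for GPR39, 3.46 for ZHX2, 3.57 for DNAJC6, 3.51 for ARHGAP42, 3.31 for TRPS1, 3.57 for SH3RF1, 4.11 for ZSWIM6, 3.54 for FGD4 and 3.45 for ZCCHC7, and -0.82 for SFPQ and 1.40 for ESR1. SFT2D3 had -7.99 (edgeR adjusted p = 0.0186), which turned to 1.99 (0.823) without sgNONO DMSO replicate 2 and was lost without sgControl DMSO replicate 1 (-7.60, 0.0544), 2 (-7.36, 0.062) or 3 (-12.09, 0.0583) and with only the compared groups in the fit (-7.99, 0.0516).

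By list, the 22Rv1 interaction went down for DBHS genes (2 higher, 7 lower; 2 and 10 adjusted over the list alone; camera adjusted p = 5.33e-07, 0.00327 with an estimated correlation). The 7 other called lists of 22Rv1 were lost with it: cholesterol synthesis (1 higher, 14 lower; the same alone; camera adjusted p = 7.36e-05; adjusted p = 0.21 with an estimated correlation), G2 and mitosis (14 lower, 16 alone; 0.000832; adjusted p = 0.119 with an estimated correlation), ATF4 targets (12 higher, 1 lower; 15 and 1 alone; 0.00468; adjusted p = 0.613 with an estimated correlation) and the unfolded protein response (9 lower; 1 higher and 10 lower alone; 0.0292; adjusted p = 0.613 with an estimated correlation). Immediate early genes (12 higher, 2 lower; 12 and 3 alone; camera adjusted p = 0.0378; adjusted p = 0.287 with an estimated correlation), breast line markers (4 higher, 2 lower; the same alone; 0.00468; adjusted p = 0.0567 with an estimated correlation) and lineage factors (5 higher, 3 lower; the same alone; 0.0186; adjusted p = 0.183 with an estimated correlation) were the others, and for lineage factors the median was -0.03 where the mean was 0.26. In MCF7 the called lists were DBHS genes (1 higher, 5 lower; 1 and 6 adjusted over the list alone; camera adjusted p = 0.000285; adjusted p = 0.0711 with an estimated correlation), lineage factors (5 higher; 5 alone; 0.000531; adjusted p = 0.113 with an estimated correlation), the unfolded protein response (7 lower, 10 alone; 0.000285; adjusted p = 0.256 with an estimated correlation) and breast line markers (3 higher; 3 alone; 0.000869; adjusted p = 0.0711 with an estimated correlation).

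Of 40 regroupings of the 12 libraries with the treatment redrawn, 3 in 22Rv1 and 5 in MCF7 called as many genes as the real one, 5823 and 1911, with highest others of 6683 and 2728. With the guide redrawn it was 1 in 22Rv1, the real grouping itself (highest other 5211) and 2 in MCF7 (highest other 3210). Each other regrouping that called as many kept 1 of the 2 real splits, so it carried a real treatment or guide effect rather than the interaction. Those that kept neither mixed the groups and called 0 genes at most by edgeR. These redraws therefore decide nothing on chance. With guide and treatment effects fitted without an interaction and the residuals redrawn over the 12 libraries, 1 of 100 assignments, the real one, called as many genes by limma in each line. That share argues against a chance assignment of libraries. It says nothing on chance differences between cultures, clones or pools, since libraries were the units redrawn. The real counts were 5868 and 1687 and the highest others 1185 and 3.

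The first pattern weighed is the lower level of long genes with SKBG-1 (R) in sgControl cells. Transcript length in place of span was argued against by the partial rank correlations given transcript length (-0.18 in 22Rv1, -0.25 in MCF7), and a bias of 1 library as the whole cause by the weakest values with 1 library left out (-0.28 and -0.32). A length bias between libraries stayed open, since 2 libraries of 1 group differed by a rank correlation of up to 0.16 in 22Rv1 and 0.26 in MCF7. These largest values were taken over all 6 groups of a line, also those outside this comparison, so they may overstate the spread of the libraries compared. An effect that needs NONO also stayed open, with values of 0.01 in 22Rv1 and -0.02 in MCF7 sgNONO cells, the latter not stable, at -0.18 without sgNONO DMSO replicate 2 against -0.37 in sgControl cells.

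The second pattern is the level of single-exon genes inside introns of other genes with SKBG-1 (R) in sgControl cells. In 22Rv1 the 325 such genes had a median of 0.06, with 45 called higher and 33 lower. Over all 18231 genes tested there, 4576 were higher and 4922 lower. The single-exon genes inside introns lay 0.15 above those outside other genes in 22Rv1 (95% bootstrap interval 0.06 to 0.25), which reads from unspliced RNA of the surrounding gene could give, while a rise of all single-exon genes was argued against by the median of -0.09 for those outside. In MCF7 the difference of 0.06 (-0.07 to 0.18) left such reads open, since the interval includes 0, the bound set before, but also holds the 0.15 of 22Rv1, so that bound excluded nothing here, and the median of 0.14 outside left a rise of all single-exon genes open. In sgNONO cells the difference was 0.17 (0.10 to 0.26) in 22Rv1, which argued against a need for NONO for that difference, and 0.06 (-0.02 to 0.16) in MCF7, which left it open. The medians in sgNONO cells, 0.03 and 0.04, decided nothing on a need for NONO. With SKBG-1 (S) in sgControl cells the difference was 0.09 in 22Rv1 (0.04 to 0.13) and 0.09 in MCF7 (0.02 to 0.15), so it was not particular to SKBG-1 (R).

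The third pattern is a set of 18 genes, among them NEB, VCAM1, CXCL2 and CCL2, found in all 3 22Rv1 sgControl DMSO libraries and under 0.05 CPM in each sgNONO DMSO library. In the other groups 100% of their 35 appearances were in 1 of the 3 libraries, which reads or RNA from other samples could give. The median ratio of the highest to the next library was 14.7. Summed over the set, SKBG-1 (R) libraries held 0.715, 2.95 and 20.3 CPM in sgControl and 1.95, 20.3 and 1.79 CPM in sgNONO cells. SKBG-1 (S) libraries held 1.47, 10.9 and 0.576 CPM, and 11.7, 1.69 and 0.553 CPM. Libraries of 1 group share treatment and guide, so these values argue against either as the source of the single-library appearances. An effect of the guide alone was argued against by the sums of the sgControl libraries with compound, each below those with DMSO. A guide effect limited to cells without compound stayed open, since the set was defined by the guides in DMSO. The genes also appeared in subsets. NEB stood at 11.1 and 11.6 CPM in SKBG-1 (R) replicates 3 (sgControl) and 2 (sgNONO), with VCAM1 at 0.0377 and 0. VCAM1 stood at 2.06 and 2.62 CPM in SKBG-1 (S) replicates 2 (sgControl) and 1 (sgNONO), with NEB at 0.924 and 1.25. Summed over the set, the 3 sgControl DMSO libraries held 25.8 to 26.5 CPM and the sgNONO DMSO libraries 0.152 to 0.2 CPM.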

How the results depend on the processing

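Precision weights for splicing and the sets without single-library genes or with at least 5 CPM were chosen after the data were seen. The count of genes moved by more than 1.5 times with a fold minimum of 2 in all comparisons: 22Rv1, 1982 (SKBG-1 (R), sgControl), 617 (SKBG-1 (S)), 1181 (stereoisomers), 533 (guides), 673, 406 and 45 (the same 3 in sgNONO) and 1327 (interaction); MCF7, 1384, 25, 1176, 163, 99, 143, 7 and 953. In MCF7 it moved without the expression filter for SKBG-1 (S) to 417, the guides to 1325, SKBG-1 (R) in sgNONO to 1089 and the stereoisomers in sgNONO to 845; with only the compared groups in the fit to 797, 141 and 51, SKBG-1 (S) in sgNONO to 8 and the stereoisomers to 7; and by DESeq2 to 344, 1147, 805, 1935 and 844. The stereoisomers in MCF7 sgNONO gave 29 genes with a replicate block, which the numbers did not warrant as pairs, and 483 among genes of at least 5 CPM. The SKBG-1 (R) effect in sgControl cells correlated with the sgNONO effect in DMSO at 0.42 in 22Rv1 and 0.31 in MCF7, with the DMSO libraries shared. With the sgNONO effect taken in SKBG-1 (S), so without shared libraries, the values were 0.01 and 0.10. Both the sharing and the treatment changed, so the move cannot be put on the sharing alone. Splicing, in the order SKBG-1 (R) in sgControl, guides in DMSO, SKBG-1 (S), SKBG-1 (R) in sgNONO, guides in SKBG-1 (R), stereoisomers: 772, 137, 180, 333, 939 and 820 events at 20 points; 21, 0, 0, 0, 7 and 1 by limma, and 830, 79, 100, 351, 1209 and 914 with precision weights. At a rate of 0.01 guides in DMSO, SKBG-1 (S) and SKBG-1 (R) in sgNONO gave 163, 221 and 578, and without a read minimum 785, 1002 and 1592, and SKBG-1 (S) gave 349 at 20 reads. With 1 library left out the counts were, in 22Rv1, 8781 to 9092 (SKBG-1 (R)), 4016 to 4927 (SKBG-1 (S)), 6296 to 6767, 2465 to 2762, 5372 to 5660, 3762 to 4322, 851 to 1239 and 4969 to 5700, and in MCF7 3213 to 3694, 65 to 91, 2558 to 2805, 319 to 806, 250 to 529, 310 to 2060, 3 to 448 and 1540 to 2001. AR ran from -1.17 to -1.12, ESR1 from -1.57 to -1.49 and NONO by guide from -3.61 to -3.52 and -1.33 to -1.13; unweighted limma then called 0 splicing events, and with weights 644 to 741, 56 to 77, 51 to 104, 233 to 334, 856 to 1074 and 690 to 828. Without weights limma called 0% of simulated differences of 20 points and 19.7% of those of 40, against 16.4% and 53% with weights. The interaction of SFT2D3 in MCF7 ran from -12.09 without sgControl DMSO replicate 3 to 1.99, reversed, without sgNONO DMSO replicate 2. Of gene list results, 96 of 384 lost their call with an estimated correlation. Of 8448 results for named genes with 1 library left out, 7608 were the same, 824 lost and 15 gained a call. Fewer libraries or genes tested explain part of this by construction; otherwise the cause was not tested.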

Other observations

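Of the tests in this part, those of splicing with precision weights were chosen after the result was seen.

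With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each gene comparison between 2 groups, 1 of 10 splits called as many genes as the real one, except SKBG-1 (S) against DMSO in MCF7 sgNONO cells, where it was 2. In 22Rv1 the real counts and the highest others were 9498 and 1 for SKBG-1 (R), 5289 and 0 for SKBG-1 (S), 7244 and 0 between the stereoisomers and 3555 and 1 between the guides, and in sgNONO cells 6346 and 0, 4782 and 0, and 1623 and 1. In MCF7 they were 4183 and 0, 151 and 0, 3350 and 0, and 706 and 0, and in sgNONO cells 516 and 2, 1284 and 1799, and 142 and 0. The split with 1799 set sgNONO DMSO replicates 1 and 3 with SKBG-1 (S) replicate 2 against the other 3 libraries, which points to a structure of these samples beside the treatment.

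For splicing, 1 of 10 splits gave as many events by limma with precision weights in each of the 6 comparisons. Real counts and highest others were 830 and 0 for SKBG-1 (R) in sgControl cells, 79 and 20 between guides in DMSO, 100 and 17 for SKBG-1 (S), 351 and 18 for SKBG-1 (R) in sgNONO cells, 1209 and 0 between guides with SKBG-1 (R) and 914 and 0 between the stereoisomers.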
